A study of Mus musculus with 20 samples.

How the data were processed

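Liver RNA of 20 adult male mice was hybridised to Affymetrix arrays, 1 array per mouse. The mice were C57BL/6NCr, an inbred strain, aged 4 to 5 months per the labels. They form 4 groups of 5 by the ambient temperature at which their dams were kept during gestation, 10, 18, 23 or 30 °C. Dams of the 30 °C group were acclimated for 3 weeks before breeding and those of the 18 °C and 10 °C groups for 2 weeks, while sires were exposed for 3 days, per the labels' protocols. All litters were moved to 23 °C at birth, so that the temperatures differed only before birth, and 23 °C, the usual animal house temperature, is the control. RNA was extracted with a column kit and labelled with biotin, per the labels' protocols.

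The deposited table holds log2 expression values, 1 per probe set row and array. The submitters' processing notes name RMA, a method that corrects background, normalises by quantiles and summarises probes on the log2 scale, and the Transcriptome Analysis Console. Versions and settings were not given in the sources used here, and no genome build is named, so no coordinates are printed. The values ran from 1.18 to 19.93. Array medians over all rows, control rows included, lay between 4.46 and 4.56. The correlation between any 2 arrays over the transcript clusters was between 0.987 and 0.993. No 2 arrays held identical values. Quantile normalisation makes array distributions alike, so a shift of all transcripts together would not be seen. RMA compresses differences of dim probe sets, whose folds are then understated. The number of arrays limits the precision, and no depth applies to an array.

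Of the 28846 rows, 6640 were control rows, which were not tested as clusters and served for array measures and as a covariate, and 22206 were transcript clusters. The platform annotation gave 1 gene symbol to 19572 of them, several symbols to 0 and none to 2634, which are unnamed here. All 19572 gene identifiers matched the RefSeq gene table, used only for names, and 0 symbols changed by the match. The named clusters carry 19505 symbols, since 55 genes had over 1 cluster. None of the genes named under the rules below had over 1, and in the lists the cluster with the highest mean stood for a gene. Srebf1 was to be named whatever its values, and is not used here, because no row carries the symbol. Another gene is not reported here.

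Each transcript cluster was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 mean per group, all 20 arrays sharing 1 estimate of the spread). From this fit came 6 pairwise comparisons, a moderated F-test over the 4 groups and, from a second fit, a slope on maternal temperature given per 10 °C. All tests are two-sided. P-values were adjusted by the Benjamini-Hochberg method within each test, with a threshold of 0.05. Errors of log2 differences are limma's standard errors (SE), with n = 5 per group. The labels name 5 mice per group and no litter, dam, batch, time of day or feeding state. P-values therefore measure the spread between these arrays, and littermates, if present, would make them too small.

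A total of 47 gene lists were fixed for liver metabolism, hormone response, stress, immune response, circadian phase and the cell types that a liver sample can hold. Of these, 45 had at least 5 measured members and were tested with limma's camera, which compares a list with the other genes, at its preset correlation of 0.01 between genes. Adjustment was over the 45 lists within a comparison. Camera with a correlation estimated for each list, and fry, which asks only whether a list's own genes move, were set as alternatives at the same time. An exact permutation test of list means per array was added later. It uses the 252 splits of 10 arrays into 5 and 5, so its smallest p is 0.0079. For list members, a count adjusted over the list alone stands beside that over all genes.

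Genes were named by a fixed rule. Up to 12 called genes with 1 symbol in each direction are named in a comparison. Where fewer than 5 passed, the 5 higher and 5 lower genes with the smallest p are given as values. For the 4-group test and the slope the rule takes the 10 with the smallest p, and for each list that passed up to 4 members. A further 12 genes of glucose, lipid and bile acid metabolism were fixed by name. None of those reported passed in any comparison, and only some of their differences are printed below. Their smallest limma adjusted p was 0.388, for Cyp7a1 between 10 °C and 18 °C offspring.

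The fits and list tests were tested on simulated data in which 200 transcript clusters were changed by known amounts between the 10 °C and 23 °C groups, with 22206 clusters in the step. At log2 changes of 0.5, 1, 2 and 3, the fit called 8, 40, 50 and 49 of 50 changed clusters, and it called 4 unchanged ones. In a simulated comparison of 18 °C with 30 °C over 19505 genes, 5 of 5 lists shifted by 0.3 passed and 0 others did. The simulated genes varied independently of each other, which real genes need not do. This run therefore cannot show how often camera passes unshifted lists whose genes are correlated. With 200 clusters given a slope of 1 per 10 °C, the slope test called 199 of them and the F-test 198, beside 16 and 12 unchanged clusters.

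The groups, the tests, the lists, this rule and most alternatives were fixed before the data were examined. These alternatives were other variance models, array weights, quantile normalisation or median centring of the deposited values, filters on dim clusters, named clusters only, other thresholds, correction over all 6 comparisons together, the animal number as a block, each array left out in turn and, for the slope, the rank of the temperature. Alternatives added after seeing the data were a clock score as a covariate, the level of the background control rows as a covariate (also set beside the first principal component), the exclusion of 2 arrays and the permutation test of list means. The 3 comparisons against 23 °C share their control arrays. Their similarity was therefore set beside 100 simulated draws of unchanged groups, in which the comparisons also shared their controls. In these draws the arrays were shuffled over all groups, so the simulated controls were not the 23 °C arrays. It was also set beside the 10 splits of the 23 °C controls into 2 and 3. Up to 100 other splits of the arrays were drawn for each count. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.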

Results

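Maternal cold or warmth before birth was the variable of this study, whose title links brown fat thermogenesis of the mother to glucose tolerance of male offspring. Liver expression was measured in 20 adult sons, 5 from each maternal temperature of 10, 18, 23 and 30 °C. The offspring are named below by the maternal temperature, and single arrays by that temperature and the animal number. All arrays had Y-linked transcripts at the levels of males, with Eif2s3y at log2 9.30 to 10.67 and Kdm5d at 5.32 to 6.59. The first 2 principal components held 11.5% and 10.3% of the variance. The first averaged -14.9 in 10 °C and -4.26 in 18 °C against 17.6 in 23 °C arrays (exact p = 0.0079 and 0.040, adjusted p = 0.159 and 0.198 over the array measures). It went with the level of the background control rows (r = -0.841 over 20 arrays, and -0.809 within groups, permutation p = 0.00126, adjusted p = 0.00252 over 2 relations). For the first component of clusters above the median this relation did not pass (-0.0732 within groups, 0.754). That component averaged 14.5 in 18 °C arrays against -6.71 in 30 °C and -7.59 in 10 °C arrays. The exact p was 0.016 and 0.032, with adjusted p = 0.179 and 0.198 over the array measures.

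The livers of 10 °C offspring differed from those of 23 °C offspring in 2 of 22206 transcript clusters, both lower. Pisd-ps3, a pseudogene of phosphatidylserine decarboxylase, fell by 2.19 ± 0.36 on the log2 scale (SE, n = 5 per group, 4.58-fold, limma adjusted p = 0.048), from 10.22 ± 0.98 to 8.03 ± 0.54 (SD). The unnamed cluster TC0900000008.mm.2 fell by 3.18 ± 0.53 (SE), from 10.11 ± 1.43 to 6.93 ± 0.58 (SD), with the same adjusted p and no overlap between the groups. The Pisd-ps3 call held in 1 of 20 fits that each left out 1 array, that without 23 °C animal 23 (adjusted p = 0.00023), and ended in the other 19 (0.053 to 0.213). The call of the unnamed cluster also held without 18 °C animal 1 (0.033), so 18 of its 20 fits ended it. Without 23 °C animal 23 the count was 22 clusters, 1 higher and 21 lower, without 18 °C animal 1 it was 1, and 0 in each of the other 18 fits. Other settings ended the Pisd-ps3 call in 13 of 16 cases (0.054 to 0.756) and that of the unnamed cluster in 12 of 15 (0.054 to 0.771). At an unadjusted p under 0.05 stood 2584 clusters, 1272 higher and 1312 lower, against 1110.3 expected with no difference, and 1242 with the background level as a covariate. The groups did not overlap in 2.45% of the clusters, where chance gives 0.79%.

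Without passing, the genes with the smallest p that were higher in 10 °C than in 23 °C offspring were Vmn1r55, Ddx52, Dnaja2, Chil3 and Zfp39, at log2 differences of 0.69 to 0.88. Those lower after Pisd-ps3 were Fance (-0.83), a DNA repair protein, Dcp1b (-1.03), an mRNA decapping factor, Ppp2r2c (-0.81) and Ints1 (-0.70). All 9 had a limma adjusted p of 0.129. Vmn1r55 and Chil3 have means under 3.90, the 95th percentile of olfactory receptors, and are not above background. Negative control rows averaged higher, at 4.40 to 4.75 per array. Genes with means between 3.90 and 4.75, here Ppp2r2c (4.18) and Dcp1b (4.46), may therefore not be above background either. Fasn, fatty acid synthase, differed by -1.17 ± 0.71 (SE, adjusted p = 0.544), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, by -0.91 ± 0.57 (0.560). Pck1, an enzyme of gluconeogenesis, differed by 0.46 ± 0.28 (0.537), and Insr, the insulin receptor, by 0.22 ± 0.12 (0.486).

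As groups, 8 of 45 gene lists passed camera between 10 °C and 23 °C, 5 lower and 3 higher, and 0 passed with an estimated correlation (smallest adjusted p = 0.735). The list of heat shock and cold-shock proteins fell by 0.55 on average over 14 genes, 12 of them lower (camera adjusted p = 4.6e-05; adjusted p = 0.735 with an estimated correlation). Adjusted over the list alone 8 members passed, and over all genes 0. Of the 8, 7 were lower and 1, the cold-induced RNA-binding protein Cirbp, higher (0.69 ± 0.24 SE), as was the list's other cold-induced member, Rbm3, without passing (0.26 ± 0.22). Among the 7 were the chaperones Hsp90aa1 (-0.88 ± 0.23), Hspb1 (-0.71 ± 0.22), Stip1 (-0.68 ± 0.23) and Dnajb1 (-0.75 ± 0.26). The list mean of 23 °C animals 1 and 2 stood apart, at 0.94 and 0.59 against -0.13 to -0.05 in the other 3 controls and -0.36 to -0.12 in 10 °C offspring, and the difference was -0.38 without animal 1 and -0.46 without animal 2. Nuclear-encoded subunits of oxidative phosphorylation fell by 0.146 on average, with 32 of 41 lower and 3 passing adjusted over the list alone, and the list means of the groups did not overlap (exact p = 0.0079, the smallest that 252 splits can give; adjusted p = 0.735 with an estimated correlation). After adjustment over the lists 0 passed this exact test in any comparison, the smallest adjusted p being 0.0893. The 3 were Atp5h (-0.58 ± 0.16), Cycs, which encodes cytochrome c (-0.44 ± 0.13), and Ndufb3 (-0.46 ± 0.14). With the level of the background control rows as a covariate the oxidative phosphorylation call ended (-0.07, adjusted p = 0.054). Those rows were brighter in 10 °C arrays, at 3.71 ± 0.02 against 3.65 ± 0.02 in 23 °C arrays (SD, exact p = 0.0079, adjusted p = 0.159 over the array measures).

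The other 6 lists that passed between 10 °C and 23 °C lost their call when single arrays were left out. Fatty acid synthesis genes fell by 0.51 on average, with 15 of 17 lower and 0 passing over the list alone (adjusted p = 0.808 with an estimated correlation). That call ended without 10 °C animal 5 (0.057), 10 °C animal 6 (-0.23, 0.395) or 23 °C animal 17 (0.066). PPARA targets, which burn fatty acids, rose by 0.30 with 24 of 26 higher (adjusted p = 0.735 with an estimated correlation), and the call ended without 10 °C animal 6 (0.11, 0.590). Macrophage markers rose by 0.27, led by Adgre1 at 0.74 ± 0.27 and with Ly6c2, whose mean is under 3.90, at -0.80 ± 0.24 (adjusted p = 0.735 with an estimated correlation), and ended without 10 °C animal 5 (0.079) or 23 °C animal 1 (0.18, 0.099). Interferon response genes rose by 0.17 (1 member passing over the list alone, the GTPase Igtp at 0.63 ± 0.17) and ended without 10 °C animal 2 (0.053), 10 °C animal 5 (0.057) or 23 °C animal 23 (0.074). Their adjusted p was 0.735 with an estimated correlation. Ribosomal proteins fell by 0.107 (adjusted p = 0.783 with an estimated correlation), ending without 10 °C animals 2 or 4 or 23 °C animals 2, 15 or 17 (0.054 to 0.104). Urea cycle and amino acid breakdown genes fell by 0.176 (0.735 with an estimated correlation), ending without 10 °C animal 6 (-0.11, 0.395) or 23 °C animals 2 (0.134) or 17 (0.093). With the background level as a covariate the calls of fatty acid synthesis (-0.25, 0.717), macrophages (0.14, 0.253) and the urea cycle (-0.09, 0.191) ended too.

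**Figure D1:**
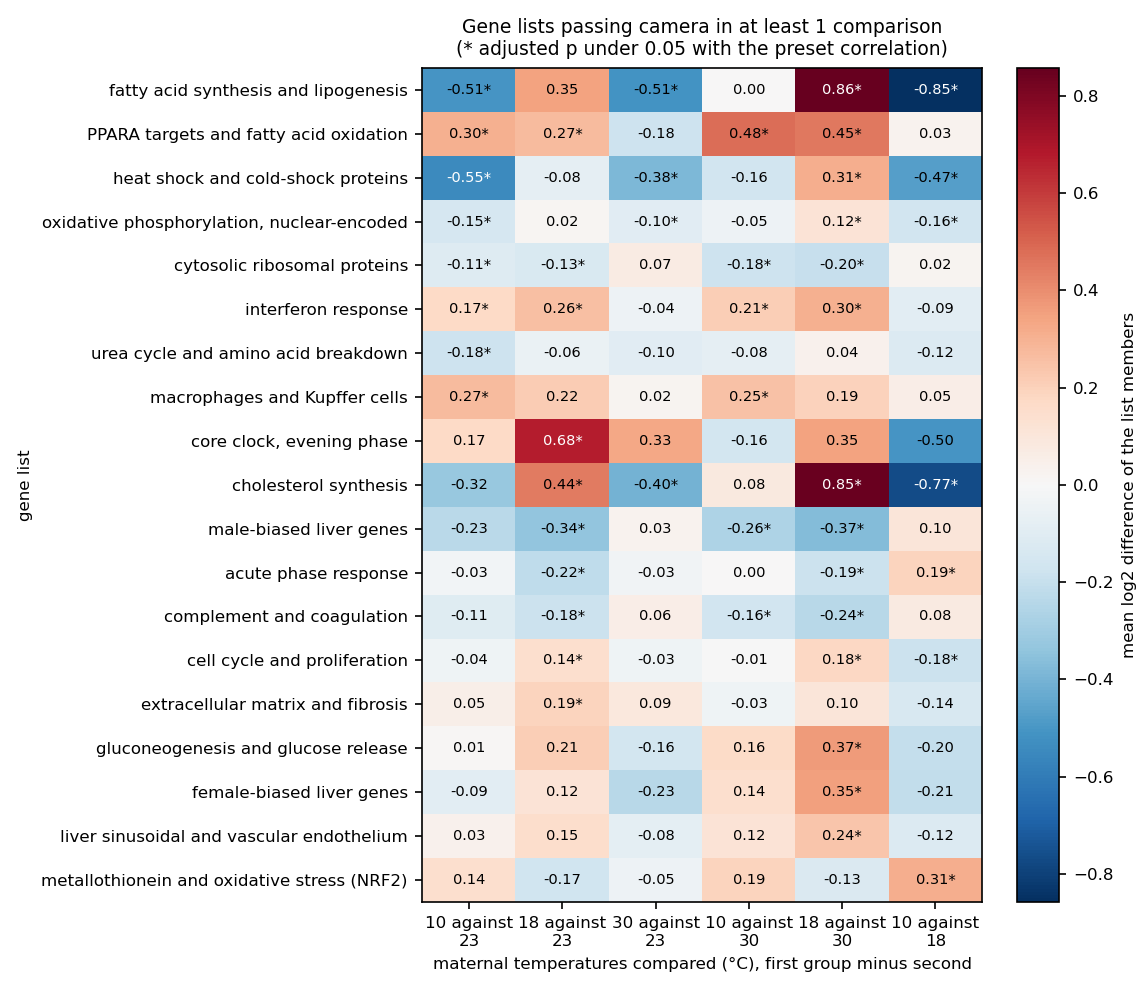
Mean log2 difference of the members of each of the 19 gene lists that passed camera in at least 1 test, by pair of maternal temperatures in °C, first group minus second, with red for higher and blue for lower. A star marks an adjusted p under 0.05 at the preset correlation, and 0 of the marked cells passed with an estimated correlation.

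Between 18 °C and 23 °C offspring 0 transcript clusters passed in limma, while 2055 stood at an unadjusted p under 0.05 (1297 with the background level as a covariate), and 3 passed with an intensity trend and robust variance, all lower. The groups did not overlap in 1.81% of clusters (0.79% by chance). The smallest adjusted p was 0.055, for Pnisr, a nuclear protein rich in serine and arginine (-0.86 ± 0.15 SE), and for Mug2, a plasma protease inhibitor (14.06 ± 0.15 in 18 °C against 15.06 ± 0.30 in 23 °C offspring, SD, n = 5 per group). Lower too were Il17b (-0.79), Gm2518 (-0.75) and Spin2c (4.96 against 5.96), at 0.249. Among the genes that were higher without passing were Dhrs7b, a dehydrogenase (0.89 ± 0.17, adjusted p = 0.0996), Rab3c (0.67, 0.210) and Acot5 (0.82, 0.249). Gm2518, Rab3c and Acot5 have means under 3.90 and are not above background. The mean of Il17b (4.69) is within the range of the negative control rows, 4.40 to 4.75. Cyp7a1 differed by 1.28 ± 0.57 (adjusted p = 0.507). Without 10 °C animal 5, 23 °C animal 2 or 23 °C animal 23 the count was 1, 2 and 3 clusters.

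Interferon response genes rose in 18 °C against 23 °C offspring by 0.26 on average, with 31 of 35 higher (camera adjusted p = 7.3e-06; adjusted p = 0.212 with an estimated correlation). The list means of the groups did not overlap (exact p = 0.0079). Adjusted over the list alone 2 members passed and over all genes 0, Ifit1, an antiviral protein (0.78 ± 0.16 SE), and Igtp (0.77 ± 0.17), while Psmb9 stood at 0.81 ± 0.26 and Tap1 at 0.56 ± 0.19. Complement and coagulation genes fell by 0.183, with 25 of 28 lower and 0 passing over the list alone (adjusted p = 0.71 with an estimated correlation), C8a at -0.64 ± 0.22 and Cfb at -0.45 ± 0.19. Ribosomal proteins fell by 0.130, with 26 of 29 lower (adjusted p = 0.795 with an estimated correlation). These 3 calls held in all 20 fits that each left out 1 array.

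In all 10 lists passed between 18 °C and 23 °C, and 0 with an estimated correlation (smallest adjusted p = 0.212). The number passing was 6 without 18 °C animal 1, 4 without 18 °C animal 5, 16 without 23 °C animal 2, 6 without 23 °C animal 23 and 6 with the clock score as a covariate. The other 7 had calls that rested on single arrays and 0 members passing over the list alone, and the adjusted p was 0.777 to 0.908 with an estimated correlation. Cholesterol synthesis genes rose by 0.44 (17 of 19 higher), ending without 18 °C animal 5 (0.31, 0.135) or 23 °C animal 23 (0.23, 0.243). Male-biased liver genes fell by 0.34, such as Gstp1 at -0.47 ± 0.17, ending without the same arrays (0.135 and 0.072). Acute phase genes fell by 0.217 with no overlap of the group means, such as Hamp, the iron hormone hepcidin, at -1.08 ± 0.45, ending without 18 °C animal 5 (0.054), with the clock score as a covariate (0.072) or with the background level as a covariate (-0.13, 0.119). Extracellular matrix genes rose by 0.19, ending without 18 °C animals 1 (0.061) or 5 (0.135) or 23 °C animal 23 (0.137). PPARA targets rose by 0.27, Cidec, a lipid droplet protein, at 1.04 ± 0.32, ending without 18 °C animals 1, 4 or 5 or 23 °C animals 1 or 17 (0.062 to 0.254). Cell cycle genes rose by 0.144, ending without 18 °C animals 1, 5 or 7, 30 °C animal 6 or 23 °C animals 15 or 23 (0.051 to 0.297). Evening-phase clock genes such as Dbp (1.78 ± 1.11) rose by 0.68. That call ended without 18 °C animals 1 or 4 or 23 °C animals 15 or 17 (means 0.33 to 0.53, adjusted p 0.098 to 0.325). The mean was 1.19 without 23 °C animal 2 and -0.16 with the background level as a covariate. It was 0.03 with the clock score as one (0.926). That outcome was fixed in advance, since the score is made of these genes minus the morning ones. The fall from 10 lists to 6 with the score includes this list. The clock score also ended the calls of PPARA targets (0.086) and cell cycle genes (0.171), which a background of brighter clusters ended as well (0.210), and the matrix genes stood at 0.30 with the background level as a covariate. Background control rows were brighter in 18 °C arrays too, at 3.71 ± 0.04 against 3.65 ± 0.02 (SD, exact p = 0.024, adjusted p = 0.179 over the array measures).

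**Figure D2:**
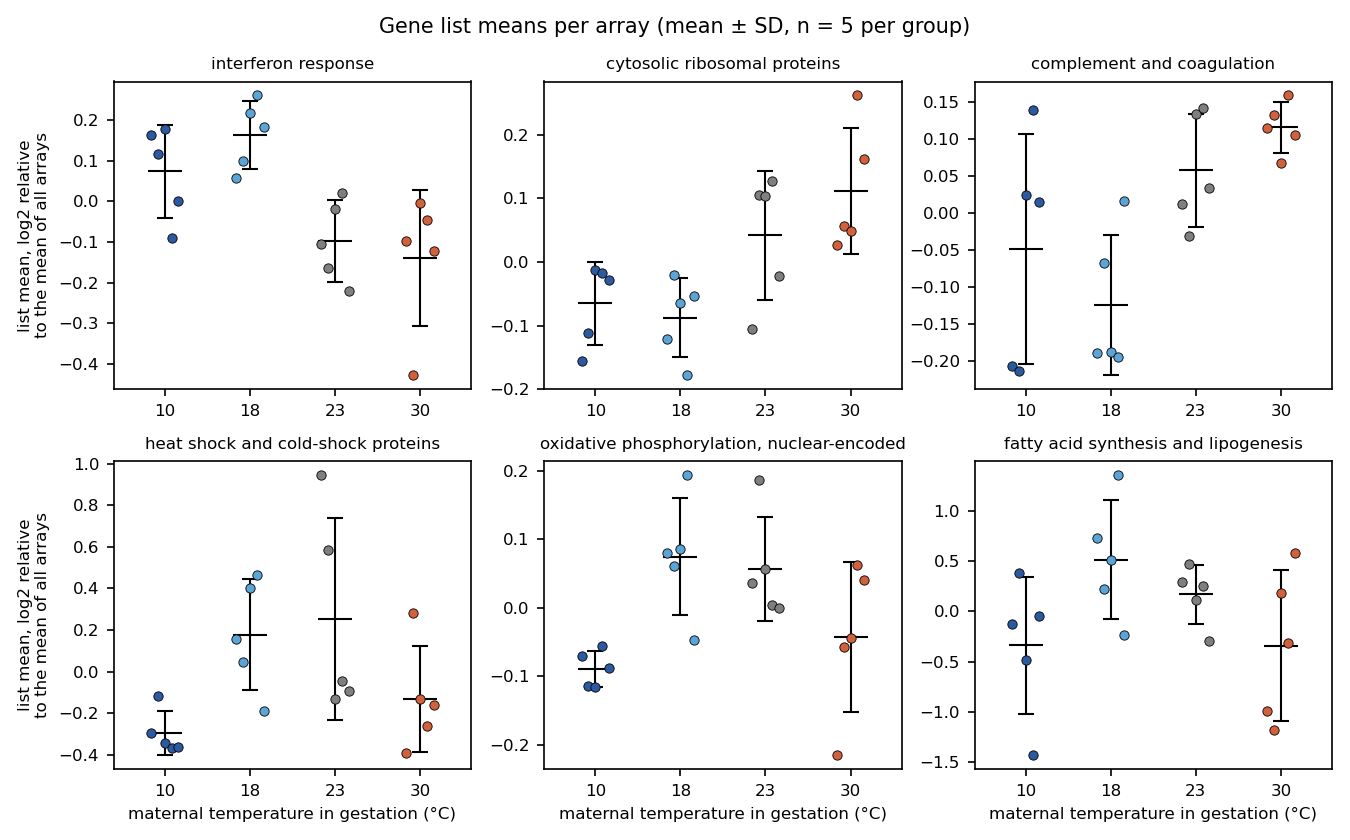
Mean of 6 gene lists on each array, in log2 relative to the mean of all arrays, against maternal temperature in °C, with points for the 5 arrays of a group and bars for mean ± SD. Interferon list means of 18 °C offspring lay above all of 23 °C and 30 °C, and oxidative phosphorylation means of 10 °C offspring lay below all of 23 °C.

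Between 30 °C and 23 °C offspring 0 clusters passed in limma and by every other variance model, and 1074 stood at an unadjusted p under 0.05, below the 1110.3 expected with no difference. The groups did not overlap in 0.75% of clusters, where chance gives 0.79%. The smallest adjusted p was 0.978. The genes with the smallest p were, among the higher, Mapkbp1 (1.12 ± 0.26 SE, n = 5 per group), Herc3 (0.76), Btk, a kinase of B cells (0.74), Zfp677 (0.61) and Gm4925 (0.58). Among the lower were Sost (-0.53 ± 0.11), Cacna1h (-0.56), Gm17455 (-0.65), 2900092C05Rik (-0.80) and Gm4349 (-0.58). Zfp677, Gm4925, Sost, Gm17455 and 2900092C05Rik have means under 3.90 and are not above background. Mapkbp1 (mean 4.00), Btk (4.31) and Cacna1h (4.16) are under the negative control rows, at 4.40 to 4.75, and may not be above background either. Scd1, a fatty acid desaturase, differed by -0.81 ± 0.28 and G6pc, which releases glucose, by -0.87 ± 0.45, both at adjusted p = 0.978.

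Heat shock and cold-shock proteins, fatty acid synthesis, oxidative phosphorylation and cholesterol synthesis were the 4 lists that passed between 30 °C and 23 °C, all lower, with adjusted p = 0.857 with an estimated correlation for each and 0 members passing over the list alone. The heat and cold shock list fell by 0.38 (13 of 14 lower, Hsph1 at -0.95 ± 0.45 SE), fatty acid synthesis by 0.51 (15 of 17 lower, Me1 at -1.12 ± 0.44) and oxidative phosphorylation by 0.0996 (31 of 41 lower, Atp5pb at -0.44 ± 0.14). The calls ended without 23 °C animal 1 for the heat and cold shock list (-0.21, 0.080), without 30 °C animal 5 for fatty acid synthesis (-0.30, 0.087), and without 30 °C animal 4 (-0.06, 0.099) or 23 °C animal 2 (0.074) for oxidative phosphorylation. Cholesterol synthesis genes fell by 0.40 (17 of 19 lower). Without 30 °C animal 5 that mean was 0.04 (0.670), without 23 °C animals 15 or 17 the call ended (0.165 and 0.0999), and without 23 °C animal 23 the mean was -0.62.

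The coldest and warmest maternal temperatures were 20 °C apart, and 0 transcript clusters passed in limma between 10 °C and 30 °C offspring, with 1501 at an unadjusted p under 0.05 and 0.98% of clusters without overlap (0.79% by chance). Pisd-ps3 came nearest, at -2.21 ± 0.36 (SE, n = 5 per group, adjusted p = 0.060). Clec2d, which encodes a lectin recognised by natural killer cells, differed by -1.27 ± 0.23 (0.180), from 14.46 ± 0.34 (SD) in 30 °C to 13.19 ± 0.49 in 10 °C offspring. Stk40 (0.68), Dnaja2, a co-chaperone (0.64), Slc23a2, a vitamin C transporter (0.76), Dtwd1 (0.56) and Olfr715b (0.69) were higher, and Ppp1r14a (-0.91), Gm15446 (-0.79) and Csta2 (-1.26) lower, at 0.662. The means of Olfr715b and Csta2 are under 3.90, not above background. With only these 2 groups in the fit 1 cluster passed, and without 23 °C animal 2 or 23 the count was 1 and 2.

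Ribosomal proteins fell in 10 °C against 30 °C offspring by 0.176, with 26 of 29 lower and no overlap of list means (camera adjusted p = 3.4e-07; exact p = 0.0079; adjusted p = 0.369 with an estimated correlation). PPARA targets rose by 0.48, with 24 of 26 higher (adjusted p = 0.369 with an estimated correlation), such as the fatty acid hydroxylases Cyp4a10 (1.42 ± 0.46 SE) and Cyp4a14 (2.26 ± 0.82) and the pantetheinase Vnn1 (1.36 ± 0.47), and by 0.28 without 10 °C animal 6. Complement and coagulation genes fell by 0.165 (24 of 28 lower, Cfb at -0.61 ± 0.19) and interferon response genes rose by 0.21 (26 of 35 higher, Irf7 at 0.85 ± 0.26), both with adjusted p = 0.369 with an estimated correlation. The interferon mean was 0.14 without 30 °C animal 5. In these 4 lists 0 members passed adjusted over the list alone. Macrophage markers rose by 0.25 and male-biased genes fell by 0.26 (0.591 and 0.696 with an estimated correlation, 0 members passing over either list alone). The macrophage call ended without 10 °C animal 5 (0.103) or 30 °C animal 8 (0.059) and was at 0.38 without 30 °C animal 4. It ended with the background level as a covariate too (0.15, 0.181), where 10 lists passed in place of 6. The male-biased call ended without 10 °C animals 2, 4 or 5 or 30 °C animals 4, 5 or 6 (0.071 to 0.298), and was at -0.40 without 10 °C animal 8 and -0.46 without 30 °C animal 8.

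Between 18 °C and 30 °C offspring 14 of 45 lists passed, 10 higher and 4 lower, and 0 passed with an estimated correlation (smallest adjusted p = 0.075) or by exact permutation. In limma 0 clusters passed, and 1823 stood at an unadjusted p under 0.05. The groups did not overlap in 1.41% of clusters (0.79% by chance). Ifit1 was nearest to passing among the higher genes, at 0.98 ± 0.16 (SE, n = 5 per group, adjusted p = 0.065), and Mug2 among the lower, at -0.99 ± 0.17 (0.065). Cyp2c38, a cytochrome P450, stood at 1.67 ± 0.37 (0.326), Glrx, a glutaredoxin, at 0.84 ± 0.19, Nubpl at 0.63 and Negr1 at 0.56. Kmt2d, a histone methyltransferase, stood at -0.71 ± 0.14 (0.143), Herc3 at -0.93, Olfr1424 at -0.70 and Rpl37a, a ribosomal protein, at -0.56. Negr1 and Olfr1424 have means under 3.90, not above background. With an intensity trend and robust variance 3 clusters passed, all lower, and without 10 °C animal 6 or 18 °C animal 1 the count was 3 and 1. Without 10 °C animal 6 and 30 °C animal 5 it was 2.

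Interferon response genes rose in 18 °C against 30 °C offspring by 0.30, with 30 of 35 higher and no overlap of list means (camera adjusted p = 2.6e-08; exact p = 0.0079; adjusted p = 0.075 with an estimated correlation). Adjusted over the list alone 3 members passed and over all genes 0, Ifit1, Usp18 (0.82 ± 0.24 SE), which trims ISG15 from proteins, and Rtp4 (0.57 ± 0.17). Complement and coagulation genes fell by 0.24 (24 of 28 lower, adjusted p = 0.238 with an estimated correlation), and 5 passed over the list alone, among them C8a (-0.82 ± 0.22), clotting factor F5 (-0.54 ± 0.15), protein C, Proc (-0.38 ± 0.12), and Cfb (-0.58 ± 0.19). Ribosomal proteins fell by 0.199 (27 of 29 lower, adjusted p = 0.306 with an estimated correlation), and 3 passed over the list alone, Rpl7 (-0.43 ± 0.12), Rps24 (-0.46 ± 0.14) and Rps16 (-0.45 ± 0.14). Group means of these 3 lists did not overlap, and fry, which tests a list's own genes, called the same 3 lists. The calls held in all 20 fits that each left out 1 array.

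Cholesterol synthesis genes rose in 18 °C against 30 °C offspring by 0.85 (19 of 19 higher, 0 passing over the list alone, such as Mvd at 1.53 ± 0.57 SE), fatty acid synthesis genes by 0.86 (16 of 17 higher, 1 passing over the list alone) and PPARA targets by 0.45 (20 of 26 higher, 3 passing over the list alone). Each had an adjusted p = 0.399 with an estimated correlation. The members that passed were Me1, a source of NADPH (1.79 ± 0.44), Acaa1b, a peroxisomal thiolase (0.99 ± 0.24), Cyp4a10 (1.72 ± 0.46) and Cyp4a14 (2.67 ± 0.82). Without 30 °C animal 5 the cholesterol mean was 0.40 (camera adjusted p = 0.0016). Oxidative phosphorylation genes rose by 0.118 (36 of 41 higher, Cox6a1 and Cox5b passing over the list alone, adjusted p = 0.399 with an estimated correlation), and by 0.07 without 30 °C animal 4. Gluconeogenesis genes rose by 0.37 (11 of 12 higher, 0 passing over the list alone, adjusted p = 0.338 with an estimated correlation), with G6pc at 1.14 ± 0.45 and Ppargc1a, a coactivator of fasting metabolism, at 0.70 ± 0.33.

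Of the remaining lists between 18 °C and 30 °C, endothelial markers rose by 0.24 (Lyve1 at 1.30 ± 0.53 SE) and acute phase genes fell by 0.187 (Itih3 at -0.51 ± 0.16), with adjusted p = 0.399 and 0.471 with an estimated correlation. The acute phase call ended with the background level as a covariate (0.054). Male-biased genes fell by 0.37 (1 passing over the list alone, Gstp1 at -0.60 ± 0.17; adjusted p = 0.515 with an estimated correlation), and by 0.56 without 30 °C animal 8. The heat and cold shock list rose by 0.31 (Rbm3 at 0.50 ± 0.22, Hsph1 at 0.91 ± 0.45 and Cirbp at -0.41 ± 0.24, 0 passing over the list alone; adjusted p = 0.460 with an estimated correlation), ending without 18 °C animals 4 (0.057) or 5 (0.068) or 30 °C animal 4 (0.075). Cell cycle genes rose by 0.179 (0.399 with an estimated correlation), ending without 18 °C animal 5 (0.060) or 30 °C animal 5 (0.117). Female-biased genes rose by 0.35 (0.471 with an estimated correlation), the 2 members passing over the list alone being Cyp4a10 and Cyp4a14, which also stand in the PPARA list. That call ended without 10 °C animals 2 or 8, 18 °C animals 1, 4 or 5, 30 °C animals 4, 5, 6 or 7 or 23 °C animal 23 (0.052 to 0.212), or with the clock score as a covariate (0.059), and stood at 0.54 against a background of brighter clusters.

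**Figure D3:**
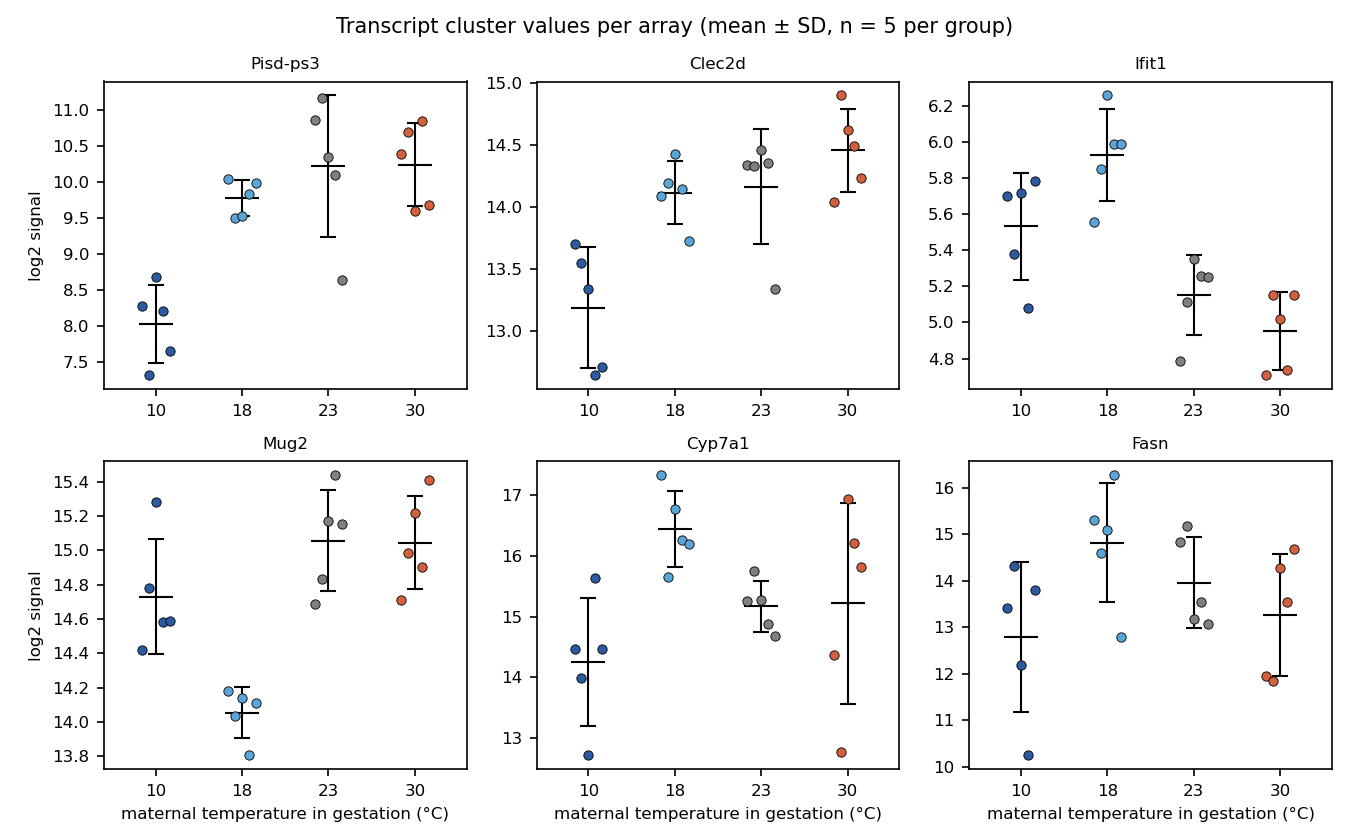
Log2 signal of 6 transcript clusters on each array against maternal temperature in °C, with points for the 5 arrays of a group and bars for mean ± SD. Pisd-ps3 in 10 °C offspring lay between 7.32 and 8.68, and in 23 °C offspring animal 23 stood at 8.64.

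The 2 cold groups differed from each other in 0 clusters by limma and with an intensity trend and robust variance, with 1799 at an unadjusted p under 0.05 and 1.42% without overlap (0.79% by chance). Cyp7a1 differed by -2.19 ± 0.57 between 10 °C and 18 °C offspring without passing (SE, n = 5 per group, adjusted p = 0.388), from 16.44 ± 0.63 (SD) at 18 °C to 14.26 ± 1.06 at 10 °C. The smallest adjusted p was 0.224, reached by Gm2518 (0.95), Pik3ap1, a signalling adaptor (0.86), and Negr1 (-0.63). Cyp3a59 (0.90), Ddx52 (0.69), Mllt10 (0.63), Pisd-ps3 (-1.75), Nol3 (-0.80), Banp (-1.10) and Mpst (-0.66) stood at 0.281. Gm2518, Negr1 and Nol3 have means under 3.90, not above background. Without 23 °C animal 23 the count was 1.

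Lists of cholesterol synthesis, fatty acid synthesis, oxidative phosphorylation and heat and cold shock genes were lower in 10 °C than in 18 °C offspring, 4 of the 7 lists that passed (each with adjusted p = 0.664 with an estimated correlation, as for all 7). Cholesterol synthesis genes fell by 0.77 (19 of 19 lower, -0.36 without 10 °C animal 6) and fatty acid synthesis genes by 0.85 (17 of 17 lower), such as Thrsp, a lipogenic regulator (-3.27 ± 0.99 SE), and Fasn (-2.02 ± 0.71). Oxidative phosphorylation genes fell by 0.164 (35 of 41 lower) with no overlap of list means (exact p = 0.0079). In these 3 lists 0 members passed over the list alone. The heat and cold shock list fell by 0.47, while the member that passed over the list alone was Cirbp, an RNA-binding protein induced by cold, which rose by 0.90 ± 0.24. Acute phase genes rose by 0.19 and cell cycle genes fell by 0.184, with 0 members passing over either list alone. The cell cycle call ended without 10 °C animal 5 (0.058), and the acute phase call without 10 °C animals 5 (0.093) or 6 (0.02, 0.654) or 18 °C animal 1 (0.061), while without 10 °C animal 4 its mean was 0.29. NRF2 and metallothionein genes rose by 0.31, with Gclc (0.81 ± 0.23), which limits glutathione synthesis, and Osgin1 (1.58 ± 0.47) passing over the list alone. That call ended without 10 °C animals 5 or 6, 18 °C animals 1, 4 or 7 or 30 °C animal 4 (0.062 to 0.335). Without 10 °C animal 6 the mean was 0.14. The call also ended with the background level (0.055) or clock score (0.092) as a covariate. The clock score also ended the acute phase call (0.092). Without 10 °C animals 2, 4 or 5 the number of lists passing was 11, 11 and 4.

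Over all 4 temperatures, 0 clusters passed a slope on maternal temperature (limma, 1809 at an unadjusted p under 0.05) or the F-test (2190). With an intensity trend and robust variance 0 and 2 passed. Per 10 °C of warmer gestation Pisd-ps3 stood at 1.11 ± 0.20 (SE, adjusted p = 0.217), Clec2d at 0.61 ± 0.12 and Mlxipl, a glucose-responsive transcription factor, at 0.40 ± 0.09. Csta2, Ppp1r14a, Gm15446, Snx17 and Yif1b followed at 0.31 to 0.67, and Stk40 and Olfr1502 at -0.32 and -0.40. In the F-test Pisd-ps3 (adjusted p = 0.068), Mug2 and Ifit1 (both 0.117) came first, followed by Gm2518, Pnisr, Herc3, Negr1, Clec2d, Kmt2d and Dhrs7b (0.178 to 0.228). Csta2, Olfr1502, Gm2518 and Negr1 have means under 3.90, not above background. The F-test count was 1 without 30 °C animal 4 and 7 without 23 °C animal 23. Ribosomal, complement and male-biased genes rose with warmer gestation, by 0.097, 0.097 and 0.162 per 10 °C, and PPARA, interferon and macrophage genes had slopes of -0.25, -0.13 and -0.14, all passing camera. Adjusted p was 0.407 with an estimated correlation for ribosomal, complement, PPARA and interferon genes, 0.613 for macrophages and 0.631 for male-biased genes. Adjusted over the list alone 5 interferon members passed, among them Irf7 (-0.46 ± 0.12) and Ifit1 (-0.36 ± 0.11), 3 ribosomal proteins, among them Rps16 (0.24 ± 0.07), 1 complement gene, Cfb (0.34 ± 0.09), and 0 in the other 3 lists. The male-biased call ended without 10 °C animal 4 or 30 °C animals 4 or 5 (0.084 to 0.101), or without 10 °C animal 6 and 30 °C animal 5 together (0.086), which left the PPARA slope at -0.17. The macrophage call ended with the background level as a covariate (-0.07, 0.168). That covariate gave 10 lists in place of 6, as did leaving out 10 °C animal 6 alone.

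Log2 differences of the 3 groups against 23 °C were correlated across clusters, which are not independent replicates, and part of this comes from the shared control arrays. For 10 °C and 18 °C, r was 0.55 against 0.50 ± 0.11 (SD) in simulated unchanged groups, with a covariance of 0.038 against 0.024 ± 0.007. For 10 °C and 30 °C, r was 0.59 against 0.50 ± 0.09 (covariance 0.033 against 0.024 ± 0.007), and for 18 °C and 30 °C 0.44 against 0.48 ± 0.10 (0.0235 against 0.0235 ± 0.0069). Of 100 draws, 32, 18 and 67 gave as large an r and 4, 10 and 52 as large a covariance. The simulated controls were not the 23 °C arrays and need not have their spread. The draws therefore do not measure the part that comes from these arrays. With the controls split so that each comparison had its own, mean r was 0.18, 0.14 and 0.03. At an unadjusted p under 0.05, 10 °C and 18 °C shared 320 higher and 417 lower clusters, where independent lists would share 55.5 and 64.2 and simulated unchanged groups 107.2 and 126.0. For 10 °C and 30 °C these were 182 and 248, against 28.1 and 34.5 and against 102.2 and 117.0. For 18 °C and 30 °C they were 125 and 186, against 21.4 and 28.6 and against 102.2 and 118.7. By expectation, unchanged groups have 1110.3 clusters at this threshold. Against 23 °C there were 2584 for 10 °C, 2055 for 18 °C and 1074 for 30 °C. The real lists of 10 °C and 18 °C were thus longer than simulated ones, and no spread over draws was kept. These counts therefore do not measure sharing beyond that from the shared controls.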

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

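The tests of clock phase, of array background and of the single array below were chosen only after the result was seen, while those of immune cells and of temperature at collection were set once the group differences had been seen but before their own values were.

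Single arrays that lay far from the other 4 of their group were found in 23 of 340 groups (6.76%, over 66 genes and 19 lists), where about 1 in 20 groups shows this by chance. Among 10 °C offspring, animal 6 stood at 3.24 for Chil3 (nearest other 3.67), 11.34 for Mlxipl (11.98) and 4.64 for Fgf21 (2.99). Animal 8 of that group stood at 3.43 for Zfp677 (nearest other 3.97), animal 2 at 11.4 for Pik3ap1 (11.7) and animal 5 at 19.2 for Scd1 (19.6). Among 18 °C offspring, animal 5 stood at 5.71 for Dtwd1 (6.16), 3.45 for Olfr715b (3.20) and 10.4 for Ppargc1a (8.92). Animal 1 of that group stood at 3.87 for Dcp1b (4.44), animal 3 at 4.58 for Herc3 (5.01) and animal 4 at 2.53 for Csta2 (3.45). Among 30 °C offspring, animal 7 stood at 2.62 for Chil3 (3.06), and animal 8 at 4.47 for Zfp677 (3.78) and 3.59 for Olfr715b (3.25). Among 23 °C offspring, animal 2 stood at 8.37 for Dhrs7b (7.78), animal 23 at 13.3 for Clec2d (14.3) and animal 17 at 10.1 for Mllt10 (9.73). Of these genes, Chil3, Fgf21, Zfp677, Olfr715b and Csta2 have means under 3.90, not above background.

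List means also held single far arrays, relative to the mean of all arrays. In 30 °C offspring these were animal 7 for PPARA targets (-0.63, nearest other -0.25), animal 5 for the interferon response (-0.43, -0.12), animal 4 for macrophages (0.41, -0.15) and animal 8 for female-biased genes (0.44, -0.28). In 10 °C offspring animal 4 stood at -0.12 for the list of heat shock and cold-shock proteins (-0.30), with its 12 heat shock genes at -0.244 (nearest other -0.339) and Cirbp and Rbm3 at 0.659.

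Control rows of the arrays, which are not among the transcript clusters tested, differed between groups in both directions by kind, without passing adjustment. Background rows averaged 3.71 in 10 °C and 3.71 in 18 °C arrays against 3.65 in 23 °C arrays (exact p = 0.0079 and 0.024, adjusted over the array measures 0.159 and 0.179). Spike-in rows averaged 3.88 in 10 °C arrays against 3.70 (exact p = 0.0079, adjusted 0.159). Negative control rows were lower, at 4.53 in 10 °C and 4.49 in 18 °C against 4.63 in 23 °C arrays (exact p = 0.048 for each, adjusted 0.204). Positive control rows averaged 8.75 and 8.74 against 8.78 (exact p = 0.413 and 0.190, adjusted 0.658 and 0.408).

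The mean of fatty acid and cholesterol synthesis genes was 0.852 ± 0.42 (SE) higher in 18 °C than in 30 °C offspring (exact p = 0.0873, n = 5 per group). With the array background as a covariate the difference was 1.004 ± 0.479, above 0.426, the level it would have to fall under if background were the whole cause. The slope on background was -3.12 ± 4.49 (SE), not apart from 0. This test therefore decides little, and a part of background in the cause is not excluded. Clock phase at collection stays open by the same measure, since with the clock score as a covariate the difference was 0.826 ± 0.424, whose error reaches below 0.426, although both list calls held with it (0.83 and 0.82 for fatty acid and cholesterol synthesis). The weight of 1 array, 30 °C animal 5, stays open too, as without it the difference was 0.524 ± 0.383, with 0.426 inside its error. Maternal temperature itself stays open, and was not tested apart from the groups.

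Interferon response genes averaged 0.302 ± 0.0763 higher in 18 °C than in 30 °C offspring (exact p = 0.0079, n = 5 per group, the smallest that 252 splits can give). With the mean of immune cell markers as a covariate the difference was 0.297 ± 0.0826, and with array background 0.329 ± 0.0872. Both stayed above 0.151, the level set for a whole cause, which argues against either, as measured here, as the whole cause. Their slopes were 0.062 ± 0.306 and -0.539 ± 0.817 (SE), neither apart from 0. These covariates could thus move the difference little, and a part in the cause is not excluded. The interferon list shares 0 members with the immune cell lists. That maternal temperature may act on interferon genes is a hypothesis found and tested on the same 10 arrays, and infection, on which the labels say nothing, stays open.

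Heat shock genes, 12 without Cirbp and Rbm3, averaged -0.718 ± 0.248 in 10 °C against 23 °C offspring (exact p = 0.0079, n = 5 per group), with controls 1 and 2 at 1.22 and 0.719, the other 3 at -0.154 to -0.0764 and 10 °C offspring at -0.513 to -0.244, and the weight of these 2 controls together was not tested. With the clock score as a covariate this was -0.730 ± 0.251 (slope on the score 0.047 ± 0.060). Mean scores were -0.31 in 10 °C and -0.55 in 23 °C offspring, and the slope was not apart from 0. The score could thus move the difference little. This argues against clock phase as the whole cause only as this score measures it, and a part in the cause is not excluded. The model is over all 20 arrays and pools the spread of the 4 groups, as do all errors of these 3 patterns. With array background as a covariate the difference was -0.563 ± 0.296, which leaves background open. Over all 20 arrays, the deviations of these genes from their group means went against those of Cirbp and Rbm3, which cold induces (Pearson r = -0.633, permutation p = 0.00665; Spearman rho = -0.605, permutation p = 0.00809; adjusted over the 2 values 0.00809, and r = -0.544 without the 2 farthest arrays). This was the 1 relation tried, with 100000 resamples, and it was thought of after the 2 gene sets were seen to differ in opposite directions between the groups. As a hypothesis, temperature of the animal or liver at collection may be part of the spread between arrays, and it was not tested whether it differs between groups.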

How the results depend on the processing

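Tests with a clock score, with the background level, without 10 °C animal 6 and 30 °C animal 5, and by exact permutation were chosen only after the result was seen. Over all alternatives, values of single genes kept direction and side of the threshold in 12119 cases, lost a pass in 62, gained one in 170 and reversed in 71. Values of gene lists did so in 1314, 327, 0 and 3. As single genes, only the 2 clusters that passed between 10 °C and 23 °C could lose a pass. Their calls held in 3 of 16 and 3 of 15 other settings, and in 1 and 2 of 20 fits without 1 array. The 12119 cases were nearly all values that passed neither before nor after, and do not measure how stable a call is. Of the 170 gains, 128 came at an unadjusted p under 0.05 and 1.5-fold. Of 55 passing list results, 29 passed in every fit that left out 1 array. Below, a pair such as 10 and 23 stands for the offspring of these maternal temperatures, and the cause was not tested unless given. Negative control rows averaged 4.40 to 4.75 per array, near the median cluster at 4.42, and background rows 3.61 to 3.75. Differences of dim clusters may therefore be held down by background, which was not tested.

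For 10 and 23, in place of 2 clusters, 0 passed with only the 2 groups in the fit, an intensity trend and robust variance, no variance moderation, array weights, quantile normalisation, clusters above the median, clusters above the olfactory receptor level of 3.90, named clusters (which leave out the unnamed one), correction over all 6 comparisons, the clock score, the background level, or without the 2 arrays. In place of 0, for 10 and 30 1 cluster passed with only the 2 groups, quantile normalisation, named clusters or a threshold of 0.10. For 18 and 23 and for 18 and 30, 3 and 3 passed with the trend and robust variance, 3 and 3 above the median, 3 and 3 above the olfactory level and 5 and 3 at 0.10, and 2 for 18 and 30 without the 2 arrays. The F-test called 2 with the trend and robust variance, 1 with array weights and 2 at 0.10. At an unadjusted p under 0.05 and 1.5-fold, which drops the adjustment, there were 610 (10 and 23), 442 (18 and 23), 156 (30 and 23), 232 (10 and 30), 408 (18 and 30) and 406 (10 and 18).

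Lists passing were 0 in all 6 comparisons and the slope with an estimated correlation, 0 in all 6 by exact permutation, and 0 by fry directionally except 3 for 18 and 30. By fry without direction they were 1 (10 and 23), 1 (18 and 23), 0 (30 and 23), 2 (10 and 30), 6 (18 and 30), 2 (10 and 18) and 2 (slope). With the clock score, which is built from the evening and morning clock lists, 6 passed for 18 and 23. With the background level 10 passed for 10 and 30 and 10 for the slope. Above the median, r between differences from 23 °C was 0.512 for 10 and 18, 0.609 for 10 and 30 and 0.385 for 18 and 30, against 0.462, 0.492 and 0.485 in simulated unchanged groups. With the controls split, which removes the shared arrays, it was 0.179 (10 and 18), 0.144 (10 and 30) and 0.0253 (18 and 30).

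Animal numbers shared between groups do not pair the arrays. Deviations of 11 pairs with the same number correlated at a mean of -0.0144 (-0.229 to 0.192, 1 over 0.1) against 0.00121 over 139 pairs with different numbers. Animals 15, 17 and 23 of the 23 °C group and animal 3 of the 18 °C group share their number with no other array. A block by number absorbs these arrays, so its comparisons against 23 °C rest on 23 °C animals 1 and 2. These are the controls that stood apart for heat shock genes, and that list stood at -1.09 (10 and 23). With the number as a replicate block, clusters passing were 0 (10 and 23), 1 (10 and 30), 1 (slope) and 1 (F-test). Lists passing were 4 (10 and 23), 1 (30 and 23) and 11 (10 and 18). Under the block these genes, none passing, reversed: Pck1 -0.18 and Irs2 -0.20 (10 and 23); Pck1 -0.28, Scd1 0.18, Igf1 0.076, Insr 0.067 and Tef -0.20 (18 and 23); Pck1 -0.48, Fgf21 -0.093, Igf1 0.081 and Cyp7a1 -0.031 (30 and 23); Igf1 -0.0049 (18 and 30); Fgf21 -0.14 (10 and 18).

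Reversed with quantile normalisation were Igf1 0.037 and Insr 0.037 (18 and 23), and with the clock score Cyp7a1 -0.088 (30 and 23). With the background level these were G6pc 0.48, Scd1 0.29 and Ppargc1a 0.080 (10 and 23), Scd1 0.37, Tef -0.15, Cry2 -0.21 and the evening clock list -0.16 (18 and 23), Irs2 0.0065 (30 and 23), Insr -0.038 (10 and 30) and Igf1 -0.042 (18 and 30). Without the 2 arrays they were Fgf21 -0.094 (10 and 23), Pck1 -0.0082, Fgf21 -0.021, Irs2 0.20, Nsdhl 0.010 and cholesterol synthesis 0.043 (30 and 23), Fgf21 -0.073 and Irs2 -0.13 (10 and 30) and Fgf21 -0.28 (10 and 18). The mean of Fgf21 over all arrays is 2.95, under 3.90. Its values here, under the block and in the fits below are not above background.

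Fits that each left out 1 array gave 0 to 22 clusters (10 and 23), 0 to 3 (18 and 23), 0 to 0 (30 and 23), 0 to 2 (10 and 30), 0 to 3 (18 and 30), 0 to 1 (10 and 18), 0 to 0 (slope) and 0 to 7 (F-test). Lists numbered 6 to 12, 4 to 16, 3 to 6, 4 to 9, 11 to 17, 4 to 11 and, for the slope, 5 to 10. Reversing results ranged as follows: Fgf21 -0.094 to 0.43, G6pc -0.50 to 0.062 and Irs2 -0.11 to 0.42 (10 and 23); Insr -0.081 to 0.040, Ppargc1a -0.13 to 0.42 and Pck1 -0.036 to 0.40 (18 and 23); Pck1 -0.12 to 0.32, Fgf21 -0.079 to 0.065, Irs2 -0.36 to 0.20, Nsdhl -0.94 to 0.010, Cyp7a1 -0.38 to 0.67 and cholesterol synthesis -0.62 to 0.043 (30 and 23); Fasn -0.85 to 0.17, Fgf21 -0.097 to 0.43 and Insr -0.021 to 0.098 (10 and 30); Igf1 -0.050 to 0.044 and Pck1 -0.062 to 0.22 (18 and 30); Scd1 -0.12 to 0.010, Fgf21 -0.28 to 0.25 and Irs2 -0.51 to 0.022 (10 and 18).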

Other observations

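The splits of the arrays were set before their result was seen, while the comparisons of array medians and of the clock score and the counts with the background level are tests chosen only after the result was seen. Of the 45 lists, 26 passed camera in none of the 6 comparisons and the slope. Thyroid hormone responsive genes came nearest, at a mean of 0.48 between 18 °C and 30 °C offspring (adjusted p = 0.0521; adjusted p = 0.306 with an estimated correlation). Next were the unfolded protein response at -0.18 and stellate cell and fibroblast markers at 0.18 between 10 °C and 23 °C (both 0.0563), immediate early genes at -0.20 between 18 °C and 30 °C (0.0633), adipose tissue markers at 0.22 between 18 °C and 23 °C (0.0637) and one-carbon metabolism at -0.13 between 10 °C and 18 °C (0.0675). The smallest adjusted p over the 7 tests was 0.125 for morning-phase clock genes, 0.132 for glycolysis, 0.229 for insulin signalling and for bile acid synthesis, 0.338 for lipoproteins, 0.497 for drug metabolism, 0.598 for glycogen metabolism, 0.629 for glucocorticoid responsive genes, 0.816 for the growth hormone and IGF axis and 0.463 for imprinted genes.

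Markers of cell types and tissues that a liver sample can hold did not pass in any of the 7 tests for skeletal muscle (smallest adjusted p = 0.116), red blood cells (0.233), gallbladder and gut (0.239), T and NK cells (0.242), periportal hepatocytes (0.315), pericentral hepatocytes (0.406), neutrophils (0.520), cholangiocytes (0.567), pancreas (0.642) and B and plasma cells (0.877). Array medians over all rows, control rows included, were 4.48 in 10 °C and 4.47 in 18 °C against 4.52 in 23 °C arrays (exact p = 0.040 and 0.016, adjusted over the array measures 0.198 and 0.179). A clock score, evening minus morning genes, did not pass between any 2 groups (exact p = 0.325 to 0.865). The animal with the lowest value among controls was 23 for Pisd-ps3 (8.64) and for Clec2d (13.3).

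Other splits of the same arrays were drawn, 100 for each count with the real split included. Chance is taken as excluded where under 5 of the 100 were as large, without correction for the number of counts tested, and splits cannot exclude shared litters. At an unadjusted p under 0.05, chance can be excluded in this sense for 10 °C against 23 °C (2584 clusters, highest other 2436, 1 split as large). The same holds for 18 °C against 23 °C (2055, 1934, 1), 10 °C against 18 °C (1799, 1631, 1) and the F-test (2190, 1833, 1). For 18 °C against 30 °C (1823, 2191, 3) the level was met narrowly, but other splits gave more. Without correction over the counts this does not exclude chance. Splits do not separate maternal temperature from the background level, with which as a covariate the counts were 1242, 1297, 1890, 1590 and 1935 in the same order. Chance cannot be excluded for 30 °C against 23 °C (1074, 1947, 47), 10 °C against 30 °C (1501, 2468, 12) and the slope (1809, 2012, 5). For the 2 clusters that passed between 10 °C and 23 °C, 4 splits were as large and the highest other gave 5. The level was met narrowly, but without correction over the counts this does not exclude chance. Most fits without 1 array ended these calls. Where 0 passed, all 100 splits were as large by construction, since no count is under 0, and this says nothing about chance. The highest other gave 13 for 18 °C against 23 °C and 4 for 18 °C against 30 °C. It gave 1 for 30 °C against 23 °C, 10 °C against 30 °C and 10 °C against 18 °C. The slope and the F-test also had 1. The split of 18 °C and 23 °C arrays with 13 clusters may point to a structure of the samples, which was not tested, while the median of the other splits was 0.

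For gene lists chance cannot be excluded in any of the 7 counts. Between 10 °C and 23 °C the real count was 8 and the highest other 15 (34 splits as large), for 18 °C and 23 °C 10 and 16 (15), for 30 °C and 23 °C 4 and 14 (75), for 10 °C and 30 °C 6 and 14 (65), for 18 °C and 30 °C 14 and 16 (6), for 10 °C and 18 °C 7 and 19 (32) and for the slope 6 and 16 (52). The median of the other splits was 6, 4, 6, 7, 5, 5 and 6 in the same order, so camera with its preset correlation also passes lists in splits other than the real one.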
